A study of Drosophila melanogaster with 4 samples.

How the data were processed

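Gene expression was measured in whole adult Drosophila melanogaster on Agilent 2-colour oligonucleotide arrays. Per the labels' protocols, flies of the temperature-sensitive collagen IV mutant DTS-3 and of the wild-type strain OreR (Oregon-R), at most 24 h old at the start, were kept at 20 °C or 29 °C for 3 days, total RNA was extracted with Trizol, and 5 µg per RNA sample was labelled with Cy3 or Cy5 by the Agilent Two-color Quick Amp kit. The series' design text calls the dye-swapped hybridisations technical, so each of the 4 combinations of genotype and temperature was treated as 1 RNA sample measured in 2 hybridisations.

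The authors deposited 8 scanner files, which were found to be 4 arrays: each array's file stands, byte for byte, under both samples whose RNA it holds. One array of each dye orientation was made at 20 °C and at 29 °C, with DTS-3 and OreR RNA on the same array, and all 4 arrays were on 1 slide scanned at 1 time, so slide and scan cannot separate them. The deposited scanner files hold spot intensities on a linear scale, per the file headers extracted with Agilent Feature Extraction 10.7.3.1. They give the median brightness of each spot and of its local background, and a processed signal that is background-subtracted and dye-normalized. The authors also deposited a value table on a log2 scale. Set against the scanner values, each of its columns is a log2 ratio of the processed signals in that sample's own dye plus 1 constant of its own, which settles the scale. The ratio is 29 °C over 20 °C by the temperatures in the names of the scanner files (rank correlation 1 over all spots). What the constants were chosen for stays unknown. The medians of its columns over all spots were 0.061 and 0.181 for OreR replicates 1 and 2, and 0.125 and -0.278 for DTS-3 replicates 1 and 2. Which of a sample's scanner files is the 29 °C array was likewise taken from those names.

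Each array carries 45020 spots, of which 1417 are controls. The 32162 Drosophila probes bear 26228 transcript or sequence IDs. Through the table of RefSeq accessions and symbols given with the data, 256 probes had 1 gene symbol, none had several and 31906 had none, so 230 symbols could be used. Other targets keep the ID of the array design, and a target below means a symbol or, without one, an ID. The probes of Col4a1, the gene mutated in DTS-3, and of its partner chain vkg are not among the named ones and were not analysed here by name.

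Background was corrected with normexp (offset 50) on median spot and median background signals, arrays were normalized by loess within and by Aquantile between arrays, and per-channel log2 values were taken, with limma 3.58.1 in R 4.3.3, and Python 3.11.15 for the rest. Control spots had weight 0 in loess and were then removed with spots marked as outliers. Repeated spots of a probe were averaged and a target was represented by its brightest probe. Of 15 symbols with more than 1 measured probe, 0 had probes that differed in call. Of these only CG1024 passed the size rule in any comparison, so for the others agreement meant that no probe passed. Ratios could still differ between probes, for lncRNA:roX1 from -0.75 to 0.32 at 29 °C over 20 °C in OreR. A target entered a comparison when its probe was well above background in both hybridisations of at least 1 RNA sample compared. 26118 targets had complete values and 106 were left out for marked spots. No Drosophila spot was saturated.

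Departures from the plan are these. The plan named mean signals, for which the median signals stand. Local backgrounds that the scanner software marked as non-uniform far exceed the spot signals on 2 arrays and disturbed the normexp fit, so they were replaced by the channel's median background and their spots left out. This change was itself chosen after seeing the data, and it matters: with the unmodified fit fewer targets pass (304 in place of 543 for OreR) the size rule, and 23 of 44 named calls do not.

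A target counted as higher or lower when its log2 ratio was at least 1 in size (2-fold) with the same sign in both dye orientations. Means are given with the SD of the 2 hybridisations, which covers technical error only. With 1 RNA sample per genotype and temperature this rule is no test. Where a probe was not well above background in either hybridisation of one side, a lower bound is given: the bright side's mean against the dim side's mean of, per hybridisation, the higher of the probe's own value and the lowest signal among probes well above background in that channel. After its values were seen, the same bound was used for CG6484 at 20 °C, where OreR was well above background in 1 hybridisation. Gene lists are described by the median log2 ratio of their measured members, the numbers past the size rule, and the percentile of the median among 10000 random lists of the same size matched on signal decile. Chosen before the data were examined were this design, 29 gene lists and the rule for named genes: Col4a1 and vkg, the 10 highest and 10 lowest targets past the size rule, up to 4 members of each list described and up to 3 bounds per direction. 19 of the 29 lists had no named target, including heat shock, collagen processing, gut enzymes, yolk and eggshell, and hemocyte genes, and the text gives every list with a measured member. 6 lists were added after the named targets were known and before values were examined. At that point the rule was also widened to every named target past the size rule, as nearly all of the top targets bear IDs only.

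A test was added after the data were seen. limma (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over 16788 targets) was fitted to the DTS-3 over OreR log2 ratio at 20 °C and at 29 °C as 2 values, which come from different RNA samples and different arrays, so that the genotype difference common to both temperatures is set against its change between them. For temperature, the 29 °C over 20 °C ratios of the 2 genotypes were tested in the same way, once in the Cy5 and once in the Cy3 channels, since within a dye the genotypes do not share arrays. A temperature fit over all arrays was tried first and left out, because the genotypes share arrays in it. Nothing says that the RNA samples came from separate rearings beyond genotype and temperature, so these p-values measure only the spread between these samples.

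The steps were tested on simulated data. For the OreR temperature comparison, with 13107 simulated targets and a noise of 0.25 log2 per channel, the size rule called 50 of 50 targets changed 4-fold, 44 of 50 changed 3-fold, 13 of 50 changed 2-fold, 1 of 50 changed 1.5-fold and 0 unchanged targets. The simulated targets were the brighter ones, with normal noise independent between channels, no marked spots and no differences between RNA samples. The real OreR comparison had 14 targets past 2-fold with opposite signs, so the 0 false calls do not carry over to it. For genotype, limma called 97 of 100 simulated targets changed 4-fold and 22 of 100 changed 2-fold, with 8 false calls among 16000 targets. The simulated variances followed the kind of distribution that eBayes assumes, a favourable case for limma. The alternatives were Agilent's processed signals, normexp offset 16, median centring, quantile or no normalization between arrays, other filters on dim probes, the median over probes, other thresholds, single hybridisations and the authors' deposited table. The number of arrays, 4, limits the precision.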

Results

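The transcriptome of whole adult flies was compared between the collagen IV mutant DTS-3 and the wild-type strain OreR at a permissive temperature (20 °C) and a restrictive one (29 °C). Collagen IV is a main component of basement membranes, and DTS-3 carries a temperature-sensitive mutation of its α1 chain. The data are 4 arrays, each with both genotypes at 1 temperature, so each of the 4 RNA samples was measured in 2 hybridisations with exchanged dyes. Between 58.7% and 74.9% of the Drosophila spots were well above background per channel, and the median ratio of spot signal to local background lay between 4.98 and 11.31, lowest for OreR at 29 °C in Cy3. All log2 ratios are means ± SD of the 2 hybridisations of 1 RNA sample per side. The laminin α chain gene LanA was the named member of the basement membrane list, as Col4a1 and vkg are not analysed here by name.

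The first question was how wild-type flies respond to 29 °C. As flies at most 24 h old were kept for 3 days, a different pace of maturation cannot be told apart from other effects of temperature. In OreR, 6 of 10 measured small RNAs of the splicing and ribosomal RNA processing machinery were higher at 29 °C than at 20 °C. The minor spliceosome RNAs snRNA:U11 (log2 ratio 2.33 ± 0.27) and snRNA:U12 (1.95 ± 0.40) passed the size rule. So did the major spliceosome RNAs snRNA:U1:21D (1.87 ± 0.37) and snRNA:U2:34ABb (1.13 ± 0.02). The nucleolar RNA snoRNA:U3:9B (1.42 ± 0.34), which serves ribosomal RNA processing, passed as well. The other measured U1 and U3 RNAs, snRNA:U1:82Eb (0.75 ± 0.26) and snoRNA:U3:54Aa (0.99 ± 0.25), did not pass. The adult cuticle protein gene Acp65Aa was the named target with the lowest ratio, at 26.7-fold lower (-4.74 ± 0.50). Gcna, a germ cell nuclear protein gene, was 3.24-fold higher (1.70 ± 0.12), and meigo, which encodes an endoplasmic reticulum nucleotide sugar transporter, was 2.70-fold higher (1.43 ± 0.35). The male-specific gene msopa was 2.89-fold lower (-1.53 ± 0.04). CG1024 (2.25 ± 0.15), CG9757 (1.90 ± 0.30), CG12204 (1.40 ± 0.07), snoRNA:Psi28S-2566 (1.38 ± 0.10) and RNaseMRP:RNA (1.21 ± 0.11), the RNA component of RNase MRP, were also higher, and CG10581 (-2.29 ± 0.15) and flap (-1.15 ± 0.07) lower.

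Of 10 small nuclear and nucleolar RNAs measured in OreR, 6 were past the size rule, all higher, and 4 were not. Their median log2 ratio was 1.26, at percentile 100 of matched random lists. No member of the accessory gland list, called accessory gland genes here and below, passed the size rule. Their place on that list was not checked in these whole-fly data. The 3 measured had a median of -0.50 (percentile 5.7), with Spn77Ba at -0.86 ± 0.04, Acp53C14a at -0.50 ± 0.45 (0.00 by its other probe) and Acp95EF at 0.00 ± 0.12. The male dosage compensation RNAs lncRNA:roX1 and lncRNA:roX2 had ratios of 0.22 ± 0.37 and 0.75 ± 0.51, with other probes of the same RNAs as low as -0.75 and 0.13. Of the mitochondrial energy genes, ATPsynbeta stood at -0.61 ± 0.53, ND-23 at -0.46 ± 0.20, COX4 at -0.03 ± 0.20 and COX5A at 0.17 ± 0.23. The 4 measured oxidative phosphorylation genes had a median of -0.25 (percentile 16.1), with none past the size rule, and the 10 of mitochondrial import and respiration -0.20 (percentile 13.1). The 4 are all among the 10, so these lists are not independent here or below. LanA had a ratio of -0.64 ± 0.01, kek1, from the list of gut stem cell genes, -0.38 ± 0.19 and the superoxide dismutase gene Sod1 -0.04 ± 0.10, within its spread of 0. The immune genes Dif (-0.05 ± 0.20) and PGRP-LA (-0.06 ± 0.57) also lay within their spread.

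Over all 16457 targets that entered, 266 were higher and 277 lower at 29 °C in OreR, and 14 differed at least 2-fold with opposite signs in the 2 orientations. Which direction held more targets depended on scaling, at 378 higher and 690 lower with Agilent's processed signals, 392 and 702 in the authors' table and 291 and 224 with median centring. Among targets without a symbol, FBtr0077061 was 30.0-fold higher (4.91 ± 0.29). With the marked local backgrounds kept, CG9757, meigo, msopa, snRNA:U2:34ABb, snoRNA:Psi28S-2566 and RNaseMRP:RNA no longer passed, and flap did not with median centring or without normalization between arrays.

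**Figure D1:**
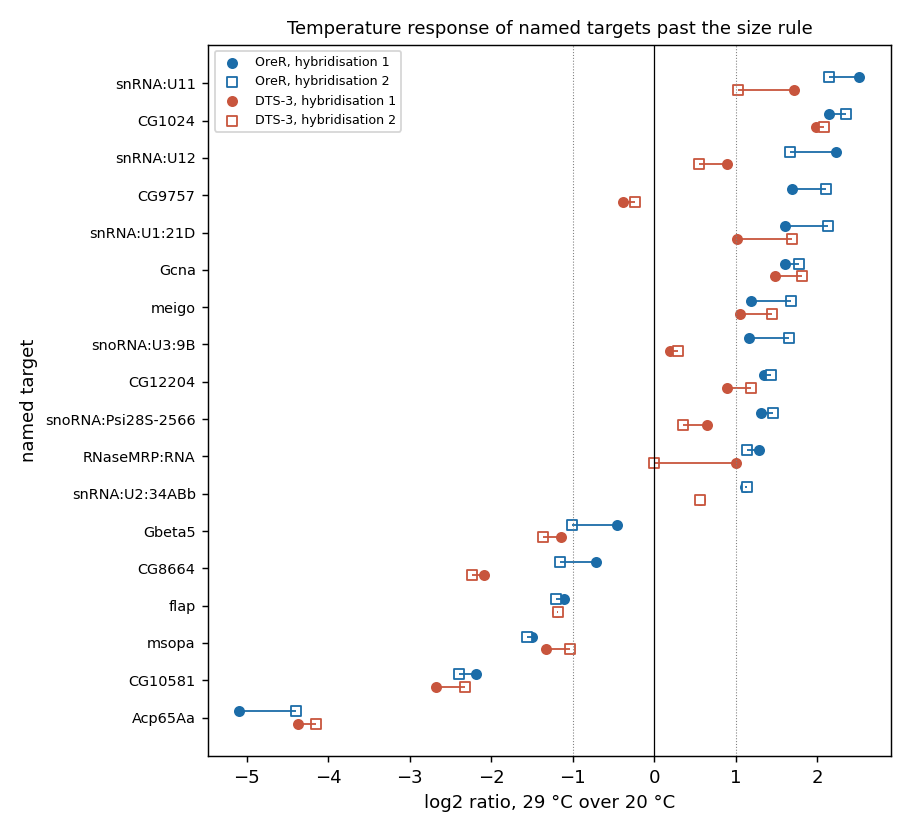
Log2 ratio of signal at 29 °C over 20 °C (horizontal axis) for every named target past the size rule in OreR (blue) or DTS-3 (red). Filled circles and open squares are the 2 hybridisations, joined by a line, and dotted lines mark 2-fold. Acp65Aa lies at -4.74 in OreR and -4.26 in DTS-3, and CG9757 at 1.90 in OreR and -0.30 in DTS-3.

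In DTS-3 flies, the same comparison asks how the mutant responds to its restrictive temperature. Acp65Aa was 19.1-fold lower at 29 °C (-4.26 ± 0.16). Gcna (1.64 ± 0.23), meigo (1.25 ± 0.28), snRNA:U11 (1.37 ± 0.49) and snRNA:U1:21D (1.35 ± 0.48) were higher, as was CG1024 (2.03 ± 0.07, and 1.24 by its other probe). The other measured U1 RNA, snRNA:U1:82Eb, stood at 0.12 ± 0.06. CG10581 (-2.50 ± 0.26), msopa (-1.18 ± 0.21), flap (-1.18 ± 0.01), CG8664 (-2.17 ± 0.10) and Gbeta5 (-1.26 ± 0.16), which encodes a G protein β subunit, were lower. The antimicrobial peptide gene Dro (drosocin) had a ratio of 0.98 ± 0.21, with 0.83 in one hybridisation. It was not well above background at 20 °C, which gives a lower bound of 1.78-fold.

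Of the 10 small nuclear and nucleolar RNAs, 2 passed the size rule in DTS-3 and 8 did not, with a median of 0.42 (percentile 99.5). The 10 named genes of mitochondrial import and respiration had a median of -0.28 (percentile 2.2) and none passed. ND-B14.7 stood at -0.53 ± 0.19, ATPsynbeta at -0.46 ± 0.31, COX4 at -0.40 ± 0.09 and ND-24L at -0.40 ± 0.27. Tim17a2 (0.36 ± 0.28) and Tim10 (0.06 ± 0.02) were the 2 positive members, against 8 negative ones. In single hybridisations, and with Agilent's processed signals, that median lay inside the central 95% of random lists. The 3 accessory gland genes had a median of -0.39 (percentile 7.0), with Spn77Ba at -0.79 ± 0.23. LanA stood at -0.62 ± 0.34, kek1 at -0.47 ± 0.04, Sod1 at 0.06 ± 0.06 and PGRP-LA at -0.22 ± 0.25.

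Of 16116 targets, 210 were higher and 213 lower at 29 °C in DTS-3, with 2 of opposite signs. The split was 436 to 328 with Agilent's processed signals, 154 to 260 with median centring and 362 to 536 in the authors' table. FBtr0079499 was 33.1-fold lower (-5.05 ± 0.28). Both genotypes shared 197 calls, 90 of them higher, where 3.0 higher and 3.7 lower ones are expected of independent lists. Named among them were CG1024, Gcna, meigo, snRNA:U11 and snRNA:U1:21D (higher) and Acp65Aa, CG10581, flap and msopa (lower). Part of the excess may come from the arrays that the genotypes share. Across 15785 targets, which are not independent replicates, the responses of the genotypes correlated with Pearson's r of 0.72 and Spearman's rho of 0.77. From arrays not shared, r was 0.51 in Cy5 and 0.54 in Cy3. With the marked local backgrounds kept, Gbeta5, meigo, msopa, snRNA:U11 and snRNA:U1:21D no longer passed in DTS-3. Without normalization between arrays, flap (-1.03), Gbeta5 (-1.31) and snRNA:U11 (1.39) did not pass. With median centring, meigo (1.20) and snRNA:U1:21D (1.28) did not.

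Whether the mutant responds differently from the wild type was read from the difference of the 2 responses. The ratios of the small nuclear and nucleolar RNAs were lower in DTS-3 than in OreR: all 10 members had a negative difference, with a median of -0.64 (percentile 0.0), and snRNA:U12 passed the size rule (-1.22 ± 0.16). CG9757 had a difference of -2.20 ± 0.19 and CG8664 a difference of -1.23 ± 0.21. snoRNA:U3:9B (-1.18 ± 0.28), snRNA:U11 (-0.96 ± 0.22) and snoRNA:Psi28S-2566 (-0.88 ± 0.32) did not pass. Acp65Aa (0.48 ± 0.34) and LanA (0.02 ± 0.33) did not pass either. Accessory gland genes had a median difference of 0.07 (percentile 63.3), oxidative phosphorylation genes -0.11 (percentile 17.8) ribosomal protein genes 0.11 (percentile 75.5) and the 3 named innate immunity genes 0.08 (percentile 55.9). Those 3 ranged from -0.16 for PGRP-LA to 1.07 for Dro, which was well above background in both hybridisations only in DTS-3 at 29 °C and had 0.99 in one hybridisation, so its value is uncertain and did not pass. Only 1 of 20 antimicrobial peptide, 0 of 16 Toll-induced peptide and 2 of 29 immune recognition and signalling genes could be named. The median of the 3 therefore cannot show whether immune genes as a whole differed.

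Of 16788 targets, 130 had a higher and 112 a lower response in DTS-3, and none had opposite signs past the threshold. The balance of higher and lower depended on the processing, at 251 to 137 with Agilent's processed signals and 80 to 45 with the marked local backgrounds kept, but 86 to 124 with median centring and 207 to 300 without replicate 2. FBtr0086620 showed the most positive difference (9.49 ± 0.02): its ratio was -5.23 ± 0.09 in OreR and 4.26 ± 0.11 in DTS-3. CG8664 no longer passed with Agilent's processed signals (-0.91), with offset 16 (-1.20) and in the authors' table (-1.05), snRNA:U12 with processed signals (-1.01), median centring (-1.34) and the marked local backgrounds kept (-1.03), and CG9757 with the last of these (-1.45), each mean having at least 1 hybridisation under 2-fold. No test of the difference was possible beyond the 2 hybridisations, as each response rests on 1 RNA sample per temperature.

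**Figure D2:**
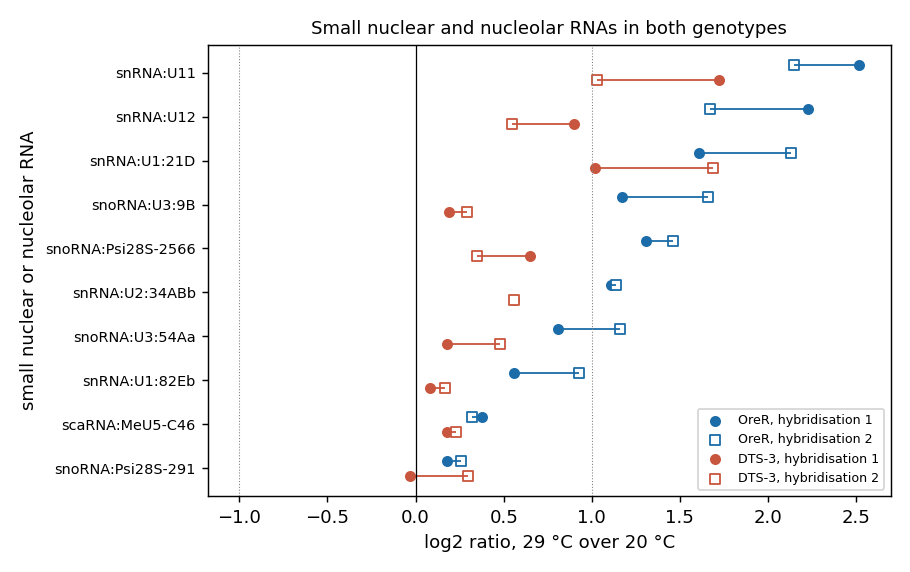
Log2 ratio at 29 °C over 20 °C (horizontal axis) of the 10 measured small nuclear and nucleolar RNAs in OreR (blue) and DTS-3 (red). Filled circles and open squares are the 2 hybridisations, and dotted lines mark 2-fold. The median is 1.26 in OreR and 0.42 in DTS-3.

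At 20 °C, where the mutation is permissive, DTS-3 and OreR were compared directly on the same arrays. CG6484 was at least 62.3-fold brighter in DTS-3, a bound equal to its measured ratio (5.96 ± 0.04). OreR was well above background in 1 of 2 hybridisations. CG8664 was 3.99-fold higher (SD 0.01 log2) and Saf6, a subunit of the SAGA coactivator, 2.48-fold higher (1.31 ± 0.25). The ribosomal protein gene RpL7 was 2.42-fold lower (-1.27 ± 0.06). Of 4 ribosomal protein genes 1 passed the size rule and the median was -0.34 (percentile 3.1), with RpL29 at -0.54 ± 0.25, sta at -0.14 ± 0.12 and RpS29 at -0.03 ± 0.00.

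The 4 oxidative phosphorylation genes all had positive ratios, with a median of 0.30 (percentile 94.1) and none past the size rule. The 10 genes of mitochondrial import and respiration, which include these 4, had a median of 0.29 (percentile 98.4), none past the rule. That median lay inside the central 95% of random lists in either single hybridisation. The long non-coding RNAs had a median of 0.40 (percentile 99.9) over 13 members, none past the rule, with lncRNA:CR32661 at 0.86 ± 0.11 (0.25 by its other probe), lncRNA:sphinx at 0.73 ± 0.30, lncRNA:CR32657 at 0.70 ± 0.35 and lncRNA:CR40465 at 0.57 ± 0.28. That median was 0.71 in one hybridisation and 0.21 in the other. The small nuclear and nucleolar RNAs had a median of -0.24 (percentile 2.5). Accessory gland genes had a median of 0.22 (percentile 84.4), LanA a ratio of 0.18 ± 0.34 and Acp65Aa 1.04 ± 0.38, below 2-fold in one hybridisation. Of the accessory gland genes, Acp53C14a stood at 0.32 ± 0.56 by its brightest probe and at 1.06 by its other probe, neither past the size rule.

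Of 16516 targets, 311 were higher and 306 lower in DTS-3 at 20 °C, with 0 of opposite signs. The split was 396 to 568 with Agilent's processed signals, 400 to 237 with median centring and 654 to 446 without replicate 2. FBtr0087232 was not well above background in DTS-3 and was at least 207-fold lower there than in OreR. With the marked local backgrounds kept, Saf6 and RpL7 no longer passed.

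At 29 °C, where the mutation is restrictive, Saf6 was 3.04-fold higher in DTS-3 (1.60 ± 0.07) and Acp65Aa 2.87-fold higher (1.52 ± 0.04). CG6484 was not well above background in OreR, and DTS-3 was at least 35.4-fold brighter by the mean of both hybridisations. Their measured log2 ratios were 5.98 and 4.50, so 1 of them lay under that bound (5.14). snoRNA:U3:9B (-1.54 ± 0.25), snRNA:U12 (-1.33 ± 0.09), snRNA:U11 (-1.32 ± 0.20) and snoRNA:Psi28S-2566 (-1.19 ± 0.20) were lower in DTS-3, together with rgr (-1.41 ± 0.22), CG9757 (-1.29 ± 0.13) and the signal peptidase subunit gene Spase22-23 (-1.20 ± 0.17). Over the 10 small nuclear and nucleolar RNAs the median was -0.87 (percentile 0.0), with 4 lower and 6 not past the rule.

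The 4 ribosomal protein genes had a median of -0.41 (percentile 1.2), none past the size rule. RpL7 stood at -0.89 ± 0.02 and RpL29 at -0.81 ± 0.24, but sta at 0.04 ± 0.08 and RpS29 at -0.00 ± 0.23. With Agilent's processed signals that median was -0.31. Dro had a ratio of 0.74 ± 0.16 and a lower bound of 1.44-fold, LanA 0.20 ± 0.01, kek1 0.31 ± 0.22 and Sod1 0.17 ± 0.01. Oxidative phosphorylation genes had a median of 0.21 (percentile 85.5), accessory gland genes 0.23 (percentile 83.4) and the 10 genes of mitochondrial import and respiration 0.03 (percentile 61.5). Acp53C14a stood at 0.42 by its brightest probe and at 0.83 by its other probe. The 14 long non-coding RNAs had a median of 0.21 (percentile 94.9), inside the central 95% of random lists. Of 15883 targets, 333 were higher and 308 lower, with 0 of opposite signs. The split was 553 to 370 with Agilent's processed signals and 263 to 262 with median centring. With the marked local backgrounds kept, of these named targets CG6484 and snRNA:U11 still passed the size rule.

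Of 838 targets past the size rule at either temperature, among those measured at both, 355 (42.4%) passed in the same direction at both. At 20 °C and at 29 °C, which have no array or RNA sample in common, 185 targets were higher in DTS-3 and 170 lower, where 6.4 and 5.2 are expected of independent lists. CG6484 and Saf6 were among them. Across 15611 targets the ratios at both temperatures correlated with r of 0.73 and rho of 0.70. In limma with the temperatures as 2 values, 1421 targets were higher and 955 lower in DTS-3 at an adjusted p under 0.05, among them 12 higher and 8 lower of 173 named targets. The mean log2 ratio ± SE was 1.45 ± 0.13 for Saf6 (adjusted p = 0.00707) and 1.28 ± 0.15 for Acp65Aa (adjusted p = 0.0136). It was -1.26 ± 0.12 for rgr (adjusted p = 0.00885), -1.08 ± 0.14 for RpL7 (adjusted p = 0.0155) and -0.98 ± 0.15 for Spase22-23 (adjusted p = 0.0215), all from limma, and each had 1 sign in 4 of 4 hybridisations. LanA did not pass (0.19 ± 0.11, adjusted p = 0.264 in limma). The number of targets past limma's threshold ranged from 807 to 3642 over the normalizations tried.

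**Figure D3:**
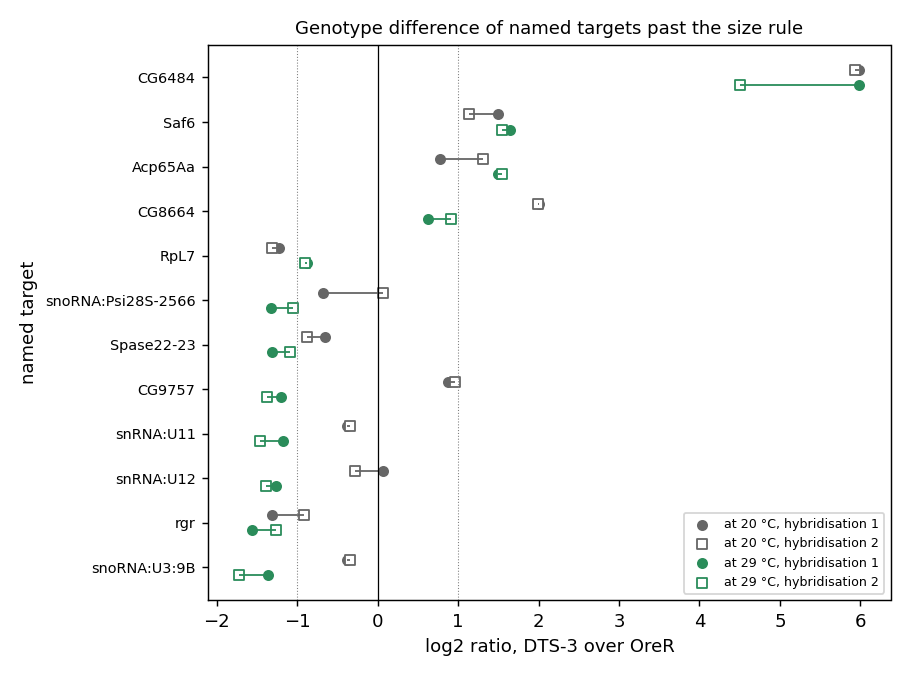
Log2 ratio of DTS-3 over OreR (horizontal axis) at 20 °C (grey) and 29 °C (green) for every named target past the size rule at either temperature. Filled circles and open squares are the 2 hybridisations, and dotted lines mark 2-fold. The points of CG6484 are measured ratios against an OreR signal near background. Their mean equals the lower bound at 20 °C but not at 29 °C. CG9757 lies at 0.92 at 20 °C and -1.29 at 29 °C.

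In the limma test of temperature over both genotypes, 922 targets passed in the Cy5 channels and 563 in the Cy3 channels, 500 of them in both with 1 direction. Acp65Aa passed in both (adjusted p = 3.54e-06 in Cy5 and 0.000239 in Cy3), as did CG10581, CG1024, Gcna, snRNA:U11 and snRNA:U1:21D. These counts ranged from 0 to 2454 over the alternatives, so no temperature call is drawn from them.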

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

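The tests in this part were chosen after the result was seen. CG9757 had ratios of opposite sign in the 2 genotypes in both hybridisations. At 29 °C over 20 °C its log2 ratio was 1.90 in OreR and -0.30 in DTS-3, a difference of -2.20. In DTS-3 the change was small (-0.38 and -0.23), near the SD between orientations over all targets there (0.26). DTS-3 over OreR went from 0.92 at 20 °C to -1.29 at 29 °C. With the marked local backgrounds kept, CG9757 no longer passed the size rule in OreR (1.21) or for the difference (-1.45). The difference between the genotypes was not tested, as there is 1 RNA sample per genotype and temperature.

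FBtr0086620 was lower at 29 °C in OreR and higher in DTS-3, a difference of 9.49 log2 units that was also not tested. It is 1 of 18 targets past the size rule in opposite directions this way, none with a symbol, whose differences run from 2.25 to 9.49. An exchange of the OreR RNA of 20 °C and 29 °C would turn the response of all targets, but the responses of the genotypes correlated at 0.51 or more from arrays they do not share. A different share of males stays open: the 3 accessory gland genes differed by at most 0.17 between the responses by their brightest probes, Acp53C14a by -0.23 in its other probe and the male-specific msopa by 0.35 ± 0.25, but abundant male transcripts would hide a small share of females, and no gene of the yolk, eggshell or female germline lists could be named here. A response of the mutant and another difference between the single RNA samples also stay open as untested explanations.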

How the results depend on the processing

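The fit with the marked local backgrounds kept and all limma counts were chosen after seeing the data. No median of a list outside the central 95% of random lists and no named target past the size rule turned its sign under any alternative run, and 0 targets past the rule were called in the opposite direction. For called targets, other thresholds, the mean of orientations, filters and single hybridisations reuse the same values and could not turn a sign. With the marked backgrounds kept, 40.9% to 56.0% of the calls remained. Without normalization between arrays, 66.3% of the temperature calls remained in OreR and 67.6% in DTS-3. Which direction held more targets did change: it turned from 130 higher and 112 lower to 86 and 124 with median centring for the difference of responses, for example, so no lean is read from the counts. With Agilent's processed signals the counts past the size rule were 1068 for OreR 29 °C over 20 °C, 764 for DTS-3, 388 for the difference of responses and 964 for the genotypes at 20 °C. With the marked backgrounds kept they were 304, 211, 125 and 276, and 263 for the genotypes at 29 °C, and 23 of 44 named calls fell below the rule. With a 1.5-fold threshold the 5 counts, in that order, were 2188, 1860, 711, 1606 and 1846, and with a 3-fold threshold 139, 93, 108, 223 and 258. By the mean of both orientations 918 targets passed in OreR and 648 in DTS-3. In the authors' deposited table the counts were 1094 in OreR, 898 in DTS-3 and 412 for the difference. Single hybridisations gave 1293 to 1353 in OreR, 742 to 931 in DTS-3, 363 to 507 for the difference, 764 to 1100 for the genotypes at 20 °C and, in limma, 1419 to 2302 for genotype. A rule asking less of the values passes more targets by construction. The cause of the other changes was not tested. Agilent's processed signals moved the median of all targets to -0.125 in OreR and 0.139 for the difference, and median centring to -0.14 for the difference and 0.136 at 20 °C. The other normalizations, filters and probe rules left each count within 1.5 times, the correlation of responses within its spread and the number of list medians outside the central 95% within 1.5 times its 9.

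In limma the genotype count was 807 with processed signals and 3642 with median centring. The temperature counts, in Cy5 and Cy3, were 0 and 0 with processed signals, 435 and 33 with offset 16, 29 and 1416 with median centring, 347 and 316 without normalization between arrays, 1877 and 2165 with the marked backgrounds kept, 0 and 3 without a filter on dim probes, and 1544 and 2454 with targets above background in every RNA sample. The median over probes gave 58 in Cy3. The unadjusted p was under 0.05 for 4086 and 4390 targets in the main setting. The dye orientation as a block leaves the mean of 2 orientations as it is. The limma test of genotype pairs the genotypes within each temperature. Leaving out saturated probes changed nothing, as there were none. The ratio of signal to background, down to 4.98 for OreR at 29 °C in Cy3, limits what dim targets can show.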

Other observations

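The limma tests and the tests on labelling, on short RNA in the extracts and on shared calls below were chosen after the result was seen. The mitochondrial ribosomal protein genes mRpL40, mRpL52 and mRpS33 had list medians from -0.08 to 0.14 over members that went both ways between the genotypes: for DTS-3 over OreR, mRpL40 stood at 0.36 ± 0.05 at 20 °C and 0.37 ± 0.19 at 29 °C, and mRpS33 at -0.29 ± 0.14 and -0.18 ± 0.05. The respiratory complex gene COX5BL had DTS-3 over OreR ratios of 0.67 ± 0.04 at 29 °C and 0.32 ± 0.18 at 20 °C, not past the size rule, while the import gene Tim17a2 had ratios of -0.63 ± 0.19 and -0.62 ± 0.05. In limma over both temperatures, lncRNA:roX2, which marks the male X chromosome for dosage compensation, was lower in DTS-3 in 4 of 4 hybridisations (-0.56 ± 0.11, adjusted p = 0.0419) by its brightest probe, but its other probe had ratios of 0.31 at 20 °C and 0.13 at 29 °C, so no direction is read for it. lncRNA:roX1 was not past the threshold (0.31 ± 0.11, adjusted p = 0.119). The non-coding RNAs lncRNA:CR32661 (0.81 ± 0.11, adjusted p = 0.0174) and lncRNA:CR40465 (0.70 ± 0.12, adjusted p = 0.03) were higher in DTS-3 by limma, with 1 sign in 4 of 4 hybridisations, though the other probe of lncRNA:CR32661 gave 0.25 at 20 °C and 0.51 at 29 °C. The testis gene Mst36Fa was not well above background in both hybridisations of any RNA sample.

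Of the 10 small nuclear and nucleolar RNAs, 6 were past the size rule at 29 °C in OreR and 2 in DTS-3, all higher. The lower of the medians of the 2 orientations in OreR was 1.14, but with 6 of 10 members past a rule that asks for both orientations this could not have been near 0, so it is no separate test of a faulty labelling reaction or array. Normalization as the cause was predicted to bring the median under 0.5 in some setting, and the lowest over 7 alternatives was 0.87. These alternatives moved the median of all OreR targets only between -0.125 and 0.028. Their scaling alone could therefore not have met the prediction. The values show only that the choice among these settings does not make the rise. All 10 members had a positive ratio in OreR, from 0.22 to 2.33, which is what a difference between single extracts in the recovery of short RNA would also give; with 1 extract per condition this and a biological response cannot be told apart. The kit primes from poly(A) tails, which most of these RNAs lack, so a change in their adenylation may enter too and was not tested.

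355 targets differed between the genotypes in the same direction at both temperatures, on separate arrays. Shared calls were at least 28.9 times those expected of independent lists. A fault of 1 array could not make a call, as the size rule asks for both arrays of a temperature, so the overlap is no test of that. It shows only that these shared calls do not rest on the arrays of 1 temperature alone. A sequence variant under 1 probe may mimic such a difference. Where a called target had another measured probe, it was asked whether that probe passed the size rule in the same direction. It did for 22 of 43 genotype calls (51.2%) and 13 of 39 temperature calls (33.3%). A probe variant cannot make a temperature call within a genotype, but by dimming a probe it could hide one. The genotype share was not the lower one (a gap of -17.9 percentage points). That share also depends on the size of the differences, which were larger for genotype. At 3-fold, 36.1% (20 °C) and 40.2% (29 °C) of genotype calls remained, against 25.6% (OreR) and 22.0% (DTS-3) of temperature calls. So the gap cannot decide on probe variants. The second probe had the same sign throughout in 74.4% of genotype calls against 89.7% of temperature calls, so probe variants stay open. For CG6484, with 1 probe, a variant or missing gene copy in OreR was not tested, and strain background and the mutation cannot be separated in this design.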
